A study of Vitis vinifera with 36 samples.

How the data were processed

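RNA was sequenced from berries of grape (Vitis vinifera), deseeded so that the whole pericarp (skin and flesh) remained. The vines were grown under a rain shelter in southern China in 2014 and carried 2 crops a year: they were pruned and forced into growth for a summer crop, then pruned and forced again for a winter crop. Per the labels, the vines were 7 years old, each group had 3 biological replicates, and 50 berries were taken from each replicate for RNA. The groups combined 2 cultivars (Victoria and Muscat Superior), the summer or winter crop, and 3 stages of the modified Eichhorn-Lorenz (E-L) scale: E-L 35, the onset of veraison, when berries soften and colour; E-L 36, intermediate sugar; and E-L 38, harvest ripeness. That made 12 groups and 36 libraries, all of which were used.

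The authors made a table per library. Per the file headers, each table gives expected counts (the estimated number of reads of a gene, with fractions where reads were shared between genes), FPKM (fragments per kilobase of transcript, scaled to the size of the library) and a transcript length in bases. The labels name Bowtie for alignment, without a version, and the series text names DESeq2 for the authors' own comparison. The genome build, the annotation release and the counting program are not given in the sources used here. Genes without reads have no line in a table and were entered as 0. The FPKM divided by the expected count per kilobase, scaled likewise, had a median of 0.993 to 0.997 over the libraries, so the 2 deposited measures hold the same quantity on different scales. Expected counts were rounded to whole numbers for testing.

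Gene identifiers of the form VIT_2 are not paired with names in the files, and 0 of the 28119 identifiers matched the supplied gene table, which belongs to another assembly. Gene lists were therefore matched by locus identifiers that had been written down before the counts were seen. These were recalled from published grape gene families and their identity was not checked against an annotation. They lack the version digit of the deposited identifiers, so a 2 was inserted before the chromosome number, which is an assumption. Of 65 identifiers written, 61 were in the files and 60 were tested. They belong to 7 lists: phenylpropanoid entry (4 loci tested), flavonoid (15), stilbene synthase (30), carotenoid and apocarotenoid (4), sugar metabolism and transport (4), abscisic acid (2) and the plastid (MEP) route to terpenoids (1). Another 14 of the 21 planned lists, among them the markers of seed, xylem and epidermis, had no identifiers and gave no result, so signal from other tissues could not be looked for.

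Counts were tested in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood F test with robust dispersion, TMM normalization, the filterByExpr filter, and a means model of the 12 groups fitted to all 36 libraries with 24 residual degrees of freedom). The filter left 19736 genes. Normalization factors ran from 0.851 to 1.202 and the common biological coefficient of variation was 0.172. A gene was called when its Benjamini-Hochberg adjusted p was below 0.05. All adjusted p-values of single loci and all counts of called genes come from this edgeR test unless another tool is named. The standard error of a log2 fold change was its size divided by the square root of F. Values per group are means of CPM (counts scaled to the library total and normalization factor) with the SD over 3 replicates. A fold against a group with 0 counts in every library is given as a lower bound, with 3 counts per library, averaged over the group, standing in for the 0.

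The comparisons were winter against summer within each cultivar and stage (6), the difference of that contrast between cultivars at each stage (3), E-L 38 against E-L 35 within each cultivar and crop (4), the difference of that contrast between crops in each cultivar (2), and Muscat Superior against Victoria over all crops and stages (1). The 5 lists with at least 4 tested loci were compared with all other genes by camera in limma 3.58.1 (preset correlation 0.01) and again with a correlation estimated from the data. They were also tested by fry, which asks whether a list moves one way on balance against no change, not against other genes. These p-values were adjusted over the lists of a comparison. List counts are given over all tested genes and adjusted over the list alone. For the terpenoid-route list, with 1 locus, the latter is the unadjusted p-value. Crop, season, sampling date and any processing batch go together in this design, and the labels give no batch.

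Loci are named by a rule set beforehand: with no gene names at hand, members of a list with the lowest p-value in each direction, plus a few identifiers with the largest change among called genes whose replicates did not overlap and whose higher mean was at least 10 CPM. Harvest ripeness was chosen for the latter after the values were seen. Replicates were checked by correlation of log2 CPM over 19555 genes and, for each pair in a group, by a chi-square of counts against binomial counting noise, over genes with at least 20 counts in the pair. Pairs below 2 per degree of freedom were called near-identical and were summed in an alternative that was chosen after seeing the data, which left 30 libraries and 2 groups with 1 library each. Another alternative chosen after seeing the data left out replicate 1 of summer Victoria at E-L 36 and at E-L 38.

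The alternatives set beforehand were DESeq2 1.42.0 size factors within edgeR, the DESeq2 Wald test, limma on log2(FPKM + 1) and on log2(FPKM + 0.1), no count filter, a stricter filter, a fit to only the groups in a contrast, the replicate number as a block, a fold change limit of 2 and each replicate left out in turn. The tests were tried on simulated data built on the comparison of winter and summer Victoria at E-L 35. There edgeR recovered 18% of genes changed by a factor of 1.5, 66% at 2, 92% at 4 and 100% at 8, and 6.8% of its calls were unchanged genes. Few genes were changed in the simulation (148 edgeR calls in all), so these shares do not give the sensitivity in the real comparison. With simulated counting noise alone the chi-square of a pair was 0.99 per degree of freedom, and with a coefficient of variation of 0.1 added it was 7.08. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.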

Results

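RNA abundance was measured in 36 libraries of deseeded grape berries, in 12 groups of 3 replicates set by cultivar, crop and ripening stage. Estimated counts summed to between 5624449 and 18606068 per library, with a median of 10.6 mega-counts (M). Summer Victoria at E-L 35 was sequenced most deeply, at 16.91 ± 1.64 M (SD, n = 3), and winter Victoria at E-L 35 least deeply, at 7.55 ± 1.89 M. The means of the other 10 groups lay between 8.98 and 13.78 M. A library listed 21184 to 23569 genes with reads, and its 10 most abundant genes held 6.3% to 16.59% of its counts. A floor of 3 counts corresponded to 0.161 to 0.533 CPM, which covers counting error only.

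Winter berries at E-L 36 and E-L 38 lay apart from the summer berries of their cultivar on the leading principal components. Victoria in winter had scores of 26.7 to 47.2 on component 1 at these stages, against -59.0 to -49.5 in summer. Muscat Superior had 54.6 to 85.6 in winter and 11.3 to 16.3 in summer. At E-L 35 the gap was narrower, with -49.7 to -44.0 in winter Victoria against -84.7 to -81.5 in summer. Replicates of a group correlated at 0.9608 to 0.9957 (Pearson, log2 CPM, across genes). Of the 18 winter replicate pairs, 8 differed by little more than counting noise (chi-square per degree of freedom 1.45 to 1.92), while 0 of the 18 summer pairs did, and the other 28 pairs ran from 2.51 to 57.74. All 3 libraries of winter Victoria at E-L 36 and of winter Muscat Superior at E-L 35 were near-identical in this sense. The spread within those groups can thus be technical, and where summing near-identical libraries changed a count of all called genes, or of list loci called between crops, by more than 1.5 times, the summed value is given too. For the list loci of the other comparisons the summed counts were not made. Standard errors and p-values of single loci and p-values of list tests were not redone with near-identical libraries summed. They take each library as a sample and can be too small where a group holds such libraries.

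**Figure D1:**
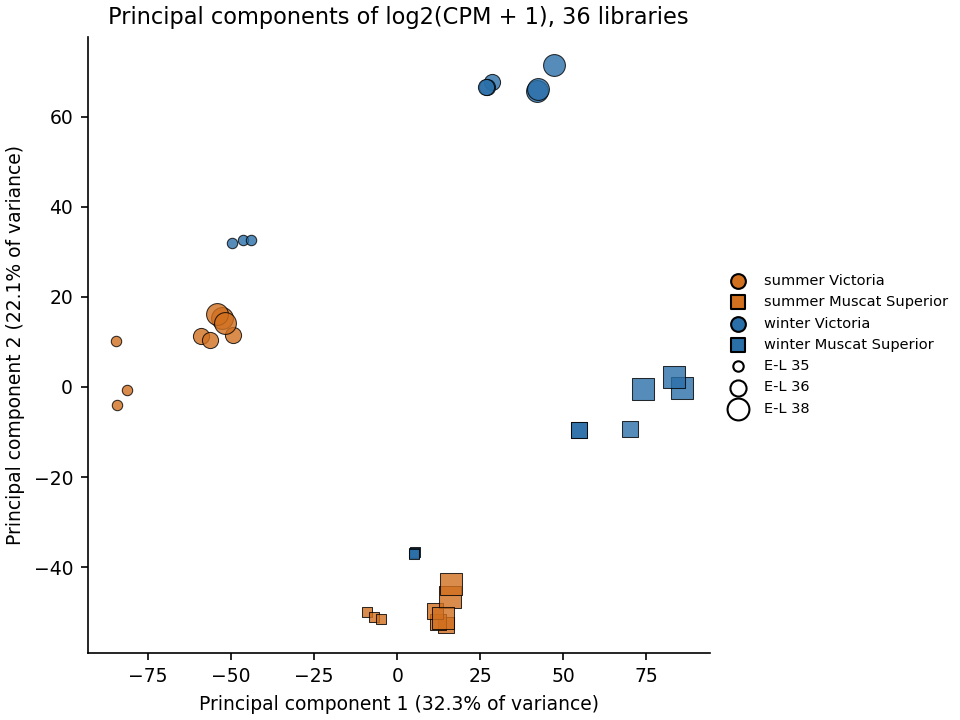
Principal components of log2(CPM + 1), with component 1 (32.3% of variance) across and component 2 (22.1%) upward, in arbitrary units; each symbol is a library, colour gives the crop, shape the cultivar and size the stage. Winter libraries at E-L 36 and 38 lie to the right of the summer libraries of their cultivar.

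The series was made to compare the transcriptomes of summer and winter berries, so the crops were compared within each cultivar and stage. The gene lists follow compounds that matter for grape quality. Phenylpropanoid entry genes turn phenylalanine into the shared precursor of flavonoids and stilbenes. Flavonoid genes lead to anthocyanins, flavonols and tannins, and stilbene synthases make resveratrol. The carotenoid list covers carotenoid formation and cleavage to aroma compounds, the sugar list invertases and sugar transporters among others, and the abscisic acid list a hormone tied to ripening. Reads of near-identical stilbene synthase loci were often shared: 0 of the 30 loci had whole-number counts in at least 80% of libraries, against 72.5% of all tested genes. Counts of single stilbene synthase loci are therefore uncertain, and their sum is given too. A list count near the share of all tested genes called is no finding about the list. By stage that share was 42.1%, 50.8% and 54.3% in Victoria and 17.6%, 42.6% and 45.1% in Muscat Superior. It was 16.7% to 18.7% for the crop effect between cultivars and 34.2% to 51.6% for ripening. For the ripening change between crops it was 42.7% in Victoria and 27.1% in Muscat Superior, and between cultivars 62.6%.

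At veraison onset in Victoria, the stilbene synthase, phenylpropanoid and flavonoid lists were higher in the winter crop. All 30 stilbene synthase loci rose, with a median log2 fold change of 5.55, and their summed level was 1080 ± 909 CPM in winter against 23.1 ± 4.82 in summer (SD, n = 3), or 557 in winter without replicate 3. All 4 phenylpropanoid entry loci rose, from a sum of 23.3 ± 10.7 to 210 ± 74.0 CPM. Of 15 flavonoid loci 10 rose and 1 fell, and their sum went from 425 ± 54.9 to 1290 ± 238 CPM. The flavonoid locus VIT_214s0068g00920 went from 8.00 ± 5.56 to 222 ± 56.1 CPM (log2 fold change 4.79, SE 0.38, adjusted p = 5.38e-10, edgeR), and the phenylpropanoid locus VIT_213s0019g04460 from 2.15 ± 0.887 to 15.8 ± 3.74 CPM (2.89, SE 0.33, adjusted p = 1.78e-07, edgeR). Of 4 sugar loci 3 rose and 0 fell, and of 4 carotenoid loci 2 rose and 1 fell; the one that fell, VIT_204s0079g00680, went from 39.2 ± 7.89 to 18.7 ± 5.26 CPM (-1.08, SE 0.28, adjusted p = 0.00329, edgeR). Neither of the 2 abscisic acid loci passed, nor did the terpenoid-route locus (log2 fold change 0.34). Its unadjusted p-value, which is what a list of 1 locus leaves, did pass. That locus also passed without summer replicate 1, and without replicate 1 of summer Victoria at E-L 36 and E-L 38. The other list counts adjusted over the list alone equalled those given. Against all other genes the camera test gave adjusted p = 5.01e-18 for stilbene synthase, 1.66e-04 for phenylpropanoid entry, 6.77e-05 for flavonoid, 0.0777 for sugar and 0.721 for carotenoid. With an estimated correlation the adjusted p = 0.0759 for stilbene synthase and 0.093 for flavonoid no longer passed, while phenylpropanoid entry kept adjusted p = 0.0213. In all, 8315 genes were called, 4299 higher and 4016 lower in winter, and 3395 of them changed at least 2-fold. The balance depends on scaling: on log2(FPKM + 0.1), which has no correction for composition, the median of all genes shifted by -0.18 and 34.3% of calls were higher in winter, against 51.7% in the edgeR test. Summing near-identical libraries left 1 carotenoid locus higher and 0 flavonoid loci lower. On both FPKM scales 1 carotenoid locus was higher and 2 flavonoid loci were lower. With any single library left out 0 or 1 carotenoid locus was higher, and without summer replicate 1 or winter replicate 1 or 3, 0 flavonoid loci were lower.

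At E-L 36 in Victoria the summed flavonoid level was 1390 ± 25.8 CPM in winter and 481 ± 127 in summer (SD, n = 3), while 7 of the 15 loci rose and 5 fell (7 and 6 adjusted over the list alone). The falls depend on the libraries: 1 locus fell with near-identical libraries summed, 2 without replicate 1 of summer Victoria at E-L 36 and E-L 38 or at E-L 36 alone, and 2 and 3 without winter replicate 1 and 2. The flavonoid locus VIT_218s0001g14310 went from 120 ± 20.8 to 648 ± 14.1 CPM (log2 fold change 2.43, SE 0.19, adjusted p = 5.3e-11, edgeR), and VIT_217s0000g07200 from 56.6 ± 11.9 to 27.2 ± 1.74 CPM (-1.06, SE 0.20, adjusted p = 6.25e-05, edgeR). Of the stilbene synthase loci 1 of 30 rose and 0 fell (0 and 0 adjusted over the list alone). Without those 2 libraries 1 rose and 6 fell, without summer replicate 1 at E-L 36 alone 1 rose and 5 fell, without summer replicate 2 or 3, 2 rose, on log2(FPKM + 1) 5 rose, on log2(FPKM + 0.1) 2 rose, and with near-identical libraries summed 0 rose. The summed level was 340 ± 31.9 CPM in winter and 287 ± 219 in summer, where replicate 1 had 34.5 and the highest replicate 414. That replicate correlated with E-L 38 replicates 2 and 3 at 0.9832 and 0.9871, above the 0.9608 and 0.9619 with its own group. Phenylpropanoid entry had 2 of 4 loci higher (2 higher and 1 lower adjusted over the list alone, with DESeq2 or without summer replicate 1). In the carotenoid list 3 of 4 loci rose, among them VIT_202s0087g00910, from 1.34 ± 0.928 to 14.9 ± 0.845 CPM (3.52, SE 0.47, adjusted p = 7.21e-07, edgeR). The sugar list had 1 of 4 loci higher and 2 lower; VIT_218s0122g00850 went from 943 ± 246 to 361 ± 10.2 CPM (-1.39, SE 0.25, adjusted p = 4.3e-05, edgeR). The carotenoid and sugar counts were the same adjusted over the list alone, and 0 of the 2 abscisic acid loci and 0 of 1 terpenoid-route locus passed either way, though the latter was higher without summer replicate 1. No list passed camera (adjusted p from 0.204 to 0.607). There were 10019 called genes, 4915 higher and 5104 lower, 4640 of them at least 2-fold. With near-identical libraries summed 6218 genes were called, 6171 of them among the 10019, with 4 flavonoid loci higher and 1 sugar locus lower; the winter group then holds a single library, assumed to vary like the others.

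In harvest-ripe Victoria the stilbene synthase loci no longer stood higher in winter: 0 of 30 rose and 8 fell (5 adjusted over the list alone), with a median log2 fold change of -1.30 and sums of 101 ± 44.4 CPM in winter and 251 ± 46.5 in summer (SD, n = 3). The summed flavonoid level stayed above summer, at 1040 ± 126 against 449 ± 26.7 CPM, with 4 of 15 loci higher and 2 lower. Much of that difference lay in 1 locus, VIT_218s0001g14310, at 590 ± 69.4 CPM in winter and 133 ± 33.2 in summer. The median log2 fold change of the list was 0.12. Phenylpropanoid entry had 1 of 4 loci higher and 0 lower (2 and 1 with DESeq2 and on log2(FPKM + 0.1), 2 and 0 on log2(FPKM + 1) and with the replicate block), and sums of 51.4 ± 19.5 in winter and 59.2 ± 12.3 CPM in summer. The carotenoid locus VIT_202s0087g00910 went from 0.521 ± 0.264 to 55.0 ± 17.2 CPM (log2 fold change 6.65, SE 0.53, adjusted p = 5.85e-11, edgeR); in its list 2 of 4 loci rose and 1 fell. In the sugar list 1 locus rose and 2 fell, of which VIT_218s0122g00850 went from 917 ± 308 to 295 ± 103 CPM (-1.63, SE 0.25, adjusted p = 3.88e-06, edgeR). The 2 abscisic acid loci and the terpenoid-route locus did not pass, and apart from stilbene synthase the counts adjusted over the list alone were equal. Among genes in no list, VIT_207s0104g01340 had 92.6 ± 7.68 CPM in winter and 0 counts in summer (at least 303-fold higher), and VIT_200s0267g00030 had 0 counts in winter and 13.2 ± 2.38 CPM in summer (at least 39.3-fold lower). No list passed camera (adjusted p from 0.168 to 0.669). Called genes numbered 10722, with 5232 higher and 5490 lower in winter and 5271 at least 2-fold. Summing near-identical libraries left 4 stilbene synthase loci, 1 flavonoid locus and 0 carotenoid loci lower. Stilbene synthase loci that fell numbered 5 and 4 without winter replicate 2 and 3, and the carotenoid fall was called without summer replicate 2 but not without any other single library. Without summer replicate 2 or winter replicate 1 a phenylpropanoid locus fell, and without the latter an abscisic acid locus rose.

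In Muscat Superior at E-L 35 the flavonoid and phenylpropanoid lists were higher in winter. Of 15 flavonoid loci 12 rose and 0 fell (13 and 0 adjusted over the list alone), and the sum was 2830 ± 86.8 CPM in winter against 931 ± 40.1 in summer (SD, n = 3). All 4 phenylpropanoid entry loci rose, from a sum of 70.6 ± 2.90 to 406 ± 7.07 CPM. The flavonoid locus VIT_216s0039g02230 went from 44.8 ± 3.01 to 155 ± 4.12 CPM (log2 fold change 1.79, SE 0.17, adjusted p = 3.76e-08, edgeR) and the phenylpropanoid locus VIT_213s0019g04460 from 37.5 ± 2.98 to 163 ± 2.74 CPM (2.12, SE 0.27, adjusted p = 3.52e-06, edgeR). Stilbene synthase transcripts were sparse, with 60.6 ± 0.835 CPM in sum in winter and 13 ± 1.52 in summer; 4 of 30 loci rose (7 adjusted over the list alone), with a median log2 fold change of 2.34, or 2.22 with the 4 loci at 0 in summer set to their bound. That count was 18 with DESeq2, 0 with limma on log2(FPKM + 1), 10 without replicate 1 of summer Victoria at E-L 36 and E-L 38, which changes only the shared dispersion, scaling and filter, and 0 with near-identical libraries summed. On log2(FPKM + 0.1) it was 12, and with any single library of the 2 groups left out 1 or 2. In the sugar list 2 of 4 loci rose (0 without summer replicate 3), and in the carotenoid list 1 of 4 fell, a call that held without summer replicate 1 but not without any other single library; 0 of the 2 abscisic acid loci passed (1 lower adjusted over the list alone, with DESeq2 or without summer replicate 3), nor did the terpenoid-route locus. Camera gave adjusted p = 3.6e-13 for flavonoid, 1.44e-05 for phenylpropanoid entry and 3.59e-06 for stilbene synthase, and 0.14 and 0.675 for sugar and carotenoid. With an estimated correlation flavonoid and phenylpropanoid entry each had adjusted p = 0.00372, and stilbene synthase lost its call at adjusted p = 0.322. Of 3468 called genes 1840 were higher and 1628 lower in winter, and 1167 changed at least 2-fold. With near-identical libraries summed, which left 1 winter library, 527 genes were called, among them 2 phenylpropanoid, 0 sugar and 0 carotenoid loci; in a fit to these 6 libraries alone 7940 genes were. The order of the comparisons depends on the fit. With all 36 libraries 3468 is the lowest of the 6 counts. In fits to 6 libraries alone 7940 is above the 7122 of Victoria at E-L 35 and the 5534 of Muscat Superior at E-L 36. The fit behind 7940 takes its spread from these libraries alone. Its 3 winter libraries were near-identical (chi-square per degree of freedom 1.47 to 1.92), so 7940 can be too high.

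At E-L 36 in Muscat Superior all 3 lists of phenolic genes were higher in winter. Stilbene synthase rose in 28 of 30 loci, from a sum of 72.4 ± 56.9 to 516 ± 204 CPM (SD, n = 3), all 4 phenylpropanoid entry loci rose, from 89.2 ± 23.4 to 490 ± 82.2 CPM, and 10 of 15 flavonoid loci rose and 0 fell, from 897 ± 186 to 2460 ± 188 CPM. The median log2 fold changes were 2.76, 2.51 and 1.46. The phenylpropanoid locus VIT_213s0019g04460 went from 37.5 ± 8.38 to 222 ± 46.9 CPM (2.56, SE 0.28, adjusted p = 3.91e-08, edgeR). The 2 abscisic acid loci parted: VIT_219s0093g00550 went from 15.1 ± 10.1 to 93.6 ± 19.6 CPM (2.62, SE 0.46, adjusted p = 5.26e-05, edgeR) and VIT_210s0003g03750 from 74.3 ± 60.4 to 8.66 ± 1.69 CPM (-3.10, SE 0.49, adjusted p = 1.16e-05, edgeR), although the replicates of the latter overlapped. The carotenoid list had 2 loci higher and 1 lower of 4, the lower being VIT_202s0087g00930, from 173 ± 76.0 to 31.5 ± 20.8 CPM (-2.47, SE 0.42, adjusted p = 3.52e-05, edgeR). In the sugar list 2 of 4 loci rose, and the terpenoid-route locus rose by a log2 fold change of 1.25. All these counts were equal adjusted over the list alone. Camera gave adjusted p = 9.07e-08 for stilbene synthase, 3.72e-04 for flavonoid and 0.00411 for phenylpropanoid entry, and 0.156 and 0.268 for sugar and carotenoid. All 3 calls were lost with an estimated correlation (adjusted p = 0.26, 0.204 and 0.108 in that order). Called genes numbered 8406, of which 4156 were higher and 4250 lower in winter and 3686 changed at least 2-fold. The stilbene synthase count was 17 with near-identical libraries summed, and 5534 genes were called in a fit to these 6 libraries alone. Summer replicate 1 stood apart from replicates 2 and 3 (chi-square per degree of freedom 57.06 and 31.09, against 12.73 between these). Without it the summer stilbene synthase sum was 40.5 CPM, 27 loci rose and 7698 genes were called. The count of stilbene synthase loci was 15 and 18 without summer replicate 2 and 3.

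In harvest-ripe Muscat Superior, 10 of 15 flavonoid loci rose and 0 fell, and their sum was 3050 ± 216 CPM in winter against 1240 ± 210 in summer (SD, n = 3). Phenylpropanoid entry had 3 of 4 loci higher and sums of 417 ± 52.9 and 129 ± 14.6 CPM, and stilbene synthase had 14 of 30 loci higher and sums of 194 ± 119 and 53.2 ± 14.9 CPM. The carotenoid locus VIT_202s0087g00910 went from 1.54 ± 0.441 to 40.4 ± 17.0 CPM (log2 fold change 4.73, SE 0.46, adjusted p = 4.25e-09, edgeR), and VIT_202s0087g00930 of the same list from 95.2 ± 52.7 to 28.6 ± 3.73 CPM (-1.74, SE 0.42, adjusted p = 0.00127, edgeR); 2 of its 4 loci rose and 1 fell. In the sugar list 2 loci rose and 1 fell, and VIT_202s0154g00090 went from 7.68 ± 4.05 to 55.5 ± 15.6 CPM (2.86, SE 0.41, adjusted p = 2.22e-06, edgeR). The terpenoid-route locus rose by a log2 fold change of 1.17, and the 2 abscisic acid loci did not pass. The counts were equal adjusted over the list alone. VIT_200s0267g00030, in no list, had 0 counts in winter and 12.1 ± 4.52 CPM in summer (at least 39.4-fold lower). Camera gave adjusted p = 2.46e-04 for flavonoid and 0.00141 for stilbene synthase, both lost with an estimated correlation (adjusted p = 0.235 and 0.473). Phenylpropanoid entry had adjusted p = 0.0526, and carotenoid and sugar 0.238 and 0.429. There were 8903 called genes, 4475 higher and 4428 lower in winter, with 3927 at least 2-fold. On log2(FPKM + 1), 9 stilbene synthase loci were called higher, without summer replicate 2 or 3, 8, and without winter replicate 2, 4; the winter sum was then 126 CPM. In the carotenoid list 1 locus rose without summer replicate 1.

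**Figure D2:**
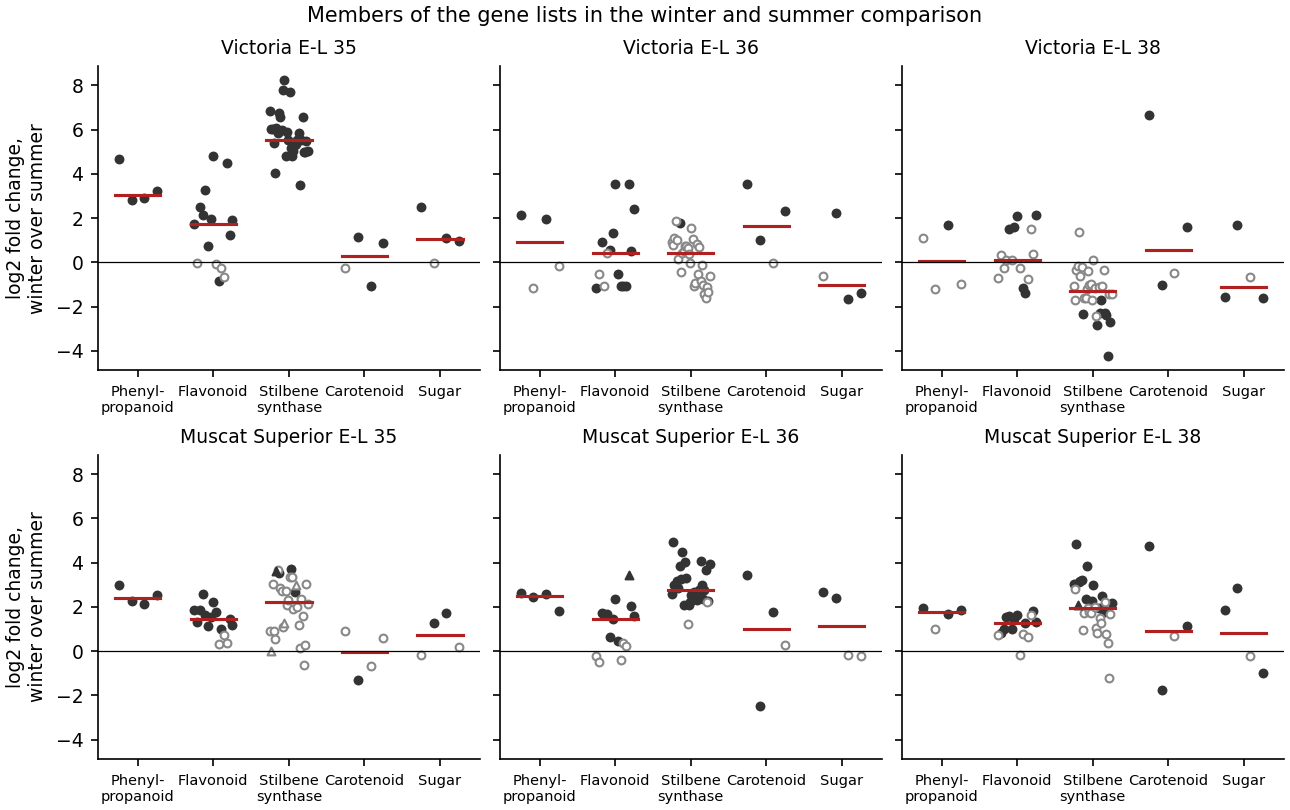
Log2 fold change of each list member, winter over summer, in the 6 comparisons; filled symbols passed the edgeR test, open ones did not, red bars are medians, and triangles mark 6 values against a group at 0 counts, drawn at their bound. All 30 stilbene synthase loci lie above 0 in Victoria at E-L 35, and 8 filled ones lie below 0 at E-L 38.

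**Figure D3:**
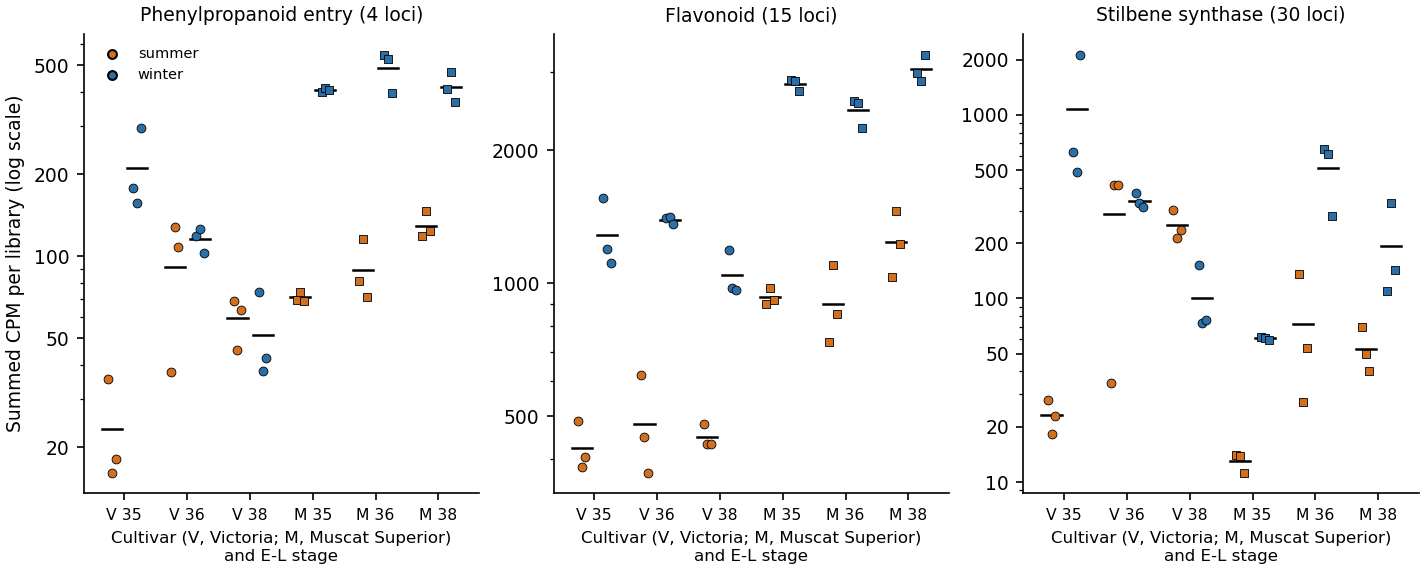
Summed CPM of 3 gene lists per library on a log scale, by cultivar and stage, with summer in orange, winter in blue and bars at the mean of 3 replicates. The winter flavonoid sums lie above all summer sums of the same cultivar and stage.

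Crop differences were shared between cultivars more often than independent calls would be, and the overlap test counted genes called in both. At E-L 35, 2012 genes were called in both cultivars and 88.1% of them changed the same way; at E-L 36 this held for 92.6% of 5588 genes and at E-L 38 for 95.7% of 6447. Genes higher in winter in both cultivars numbered 986, 2573 and 3074 at the 3 stages, where 401, 1035 and 1186 would be expected of independent calls. Between E-L 36 and E-L 38, 97.9% of the 7487 genes called at both stages in Victoria and 96.7% of 5479 in Muscat Superior changed the same way. Between E-L 35 and E-L 38 the share was 69.8% of 4915 genes and 79.1% of 2037. Across all 6 comparisons 298 genes were higher and 232 lower in winter, where independent calls would give 1.3 and 1.2; they included 3 flavonoid loci and 1 phenylpropanoid locus, all higher. Called in at least 1 comparison were 17297 genes, and 2439 were called in none. These overlaps were not recomputed with near-identical libraries summed. The 2012, 986 and 2037 genes that rest on Muscat Superior at E-L 35 could not be reached then, since fewer genes were called there. The 298 and 232 genes called in all 6 comparisons could not both be reached either. Genes are not independent replicates, and season, sampling date and any batch go with the crop in both cultivars. Calls of the same gene share its dispersion from the fit to all 36 libraries, so some excess over independent calls can arise from this alone.

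**Figure D4:**
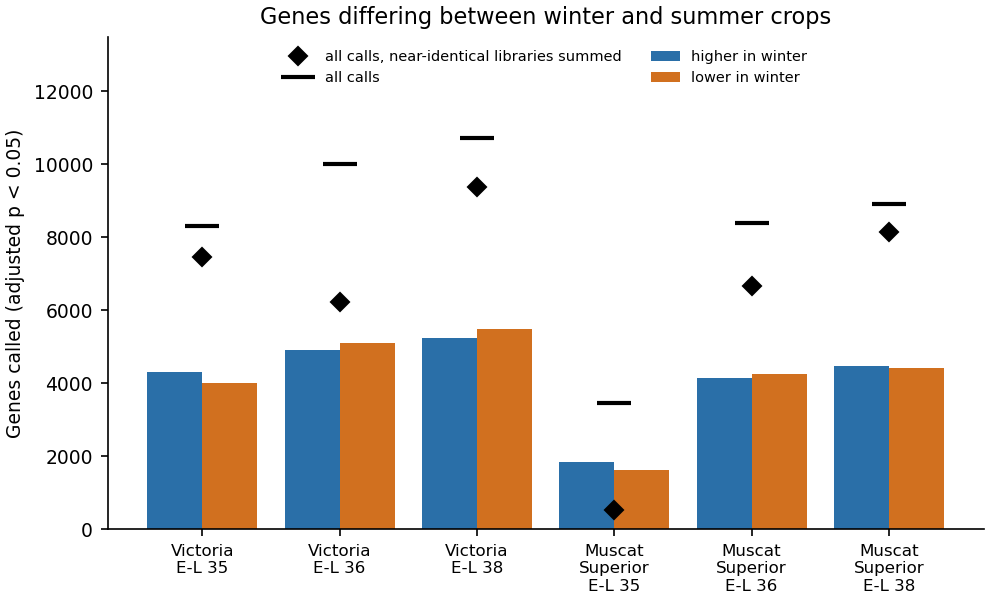
Number of genes called between winter and summer in each cultivar and stage, as bars for each direction, a dash for their total and a diamond for the total with near-identical libraries summed. The diamond is lowest in Muscat Superior at E-L 35, with 527 of 3468 genes.

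Whether the crop effect differed between cultivars was tested as an interaction, where higher means a larger winter-to-summer ratio in Muscat Superior. At E-L 36, 11 stilbene synthase loci were higher and 0 lower (16 and 0 adjusted over the list alone), and at E-L 38, 15 and 0 (25 and 0); at E-L 35 it was 0 and 4 (0 and 0). These counts vary with the scale and the libraries. At E-L 35 the loci lower were 17 with DESeq2, 26 on log2(FPKM + 1) and 13 on log2(FPKM + 0.1), and 0 (without summer Muscat Superior replicate 2) to 7 (without winter Victoria replicate 2) with a library left out. At E-L 36 the loci higher were 10, 9 and 5 on these scales and 4 (without summer Victoria replicate 2) to 23 (without summer Victoria replicate 1). At E-L 38 they were 18, 11 and 13, and 4 (without winter Muscat Superior replicate 2) to 16. Flavonoid loci were 4 higher and 2 lower at E-L 35 (5 and 3 adjusted over the list alone), 4 and 1 at E-L 36 (5 and 2) and 6 and 1 at E-L 38 (6 and 1). With a library left out they ranged over 3 to 5 and 1 to 3, 4 to 5 and 0 to 2, and 4 to 7 and 0 to 1; at E-L 36 they were 4 and 0 on log2(FPKM + 0.1) and 4 and 2 on log2(FPKM + 1). For phenylpropanoid entry 0 loci passed at E-L 35, 1 was higher at E-L 36 (2 adjusted over the list alone) and 2 at E-L 38 (2), or 1 to 2 at both with a library left out. Sugar loci were 0 higher and 1 lower at E-L 35 (1 and 2 adjusted over the list alone), 2 and 0 at E-L 36 (2 and 0) and 1 and 0 at E-L 38 (1 and 0), with 1 to 3 higher at E-L 36 when a library was left out, and carotenoid loci 0 and 1 (0 and 1), 1 and 2 (1 and 2) and 0 and 0 (1 and 1, or 0 and 1 with DESeq2, and up to 1 and 1 with a library left out). Of the 2 abscisic acid loci 0 passed at E-L 35 (2 lower adjusted over the list alone) and at E-L 38 (0), while at E-L 36 1 was higher and 1 lower (1 and 1). The terpenoid-route locus was higher at E-L 36 and E-L 38, adjusted over all genes and unadjusted. In the camera test adjusted p was 7.88e-11, 3.89e-05 and 3.5e-09 for stilbene synthase at the 3 stages, 0.0487 for sugar at E-L 36 and 0.00816 for flavonoid at E-L 38, and from 0.0518 to 0.596 for the rest. With an estimated correlation no list passed (stilbene synthase 0.46, 0.389 and 0.215, sugar 0.389, flavonoid 0.215). In all, 3567, 3688 and 3304 genes were called at E-L 35, 36 and 38, of which 1680, 1827 and 1610 were higher. Genes called in opposite directions in the cultivars with a called interaction numbered 240, 413 and 274, which was not recomputed with near-identical libraries summed. What follows is for all genes with a called interaction. With near-identical libraries summed the counts were 935, 1000 and 2006, and at E-L 36 a fit to the 4 groups alone called 1983. On log2(FPKM + 0.1), 73.8% of the calls at E-L 35 were higher against 47.1% in the edgeR test, and 64.6% at E-L 36 against 49.5%, with shifts of all genes of 0.21 and 0.10.

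Ripening from veraison to harvest changed the stilbene synthase list in opposite directions in the 2 crops of Victoria. In summer 28 of 30 loci rose and 0 fell from E-L 35 to E-L 38 (median log2 fold change 3.39), and in winter 0 rose and 29 fell (median -3.53), with equal counts adjusted over the list alone. In winter Victoria 8 flavonoid loci fell and 1 rose, and 3 of 4 phenylpropanoid entry and 3 of 4 sugar loci fell (same counts adjusted over the list alone), while in summer 3 phenylpropanoid entry loci rose (4 adjusted over the list alone) and 2 flavonoid loci rose and 2 fell (2 and 0). In summer 1 sugar locus rose and 2 fell. Of 4 carotenoid loci 0 rose and 2 fell in summer, and 1 rose and 2 fell in winter, with equal counts adjusted over the list alone. Camera gave adjusted p = 8.85e-09 for stilbene synthase in summer and 6.78e-07 in winter, and in winter 0.0157 for flavonoid and 0.0198 for sugar; with an estimated correlation these were adjusted p = 0.326, 0.261, 0.261 and 0.261. The remaining lists did not pass: in summer phenylpropanoid entry had 0.0738, carotenoid 0.238, and flavonoid and sugar 0.74; in winter phenylpropanoid entry had 0.139 and carotenoid 0.886, the latter with a median (-0.45) and a mean (0.48) of opposite sign. Of the 2 abscisic acid loci 1 fell in each crop, and the terpenoid-route locus fell by 0.51 and 0.61 on the log2 scale in summer and winter. Called genes numbered 8457 in summer (4099 higher, 4358 lower) and 10175 in winter (4872 and 5303), and 66.8% of the 4774 genes called in both changed the same way. In summer the log2(FPKM + 0.1) scale shifted all genes by -0.31 and left 24.1% of calls higher, against 48.5% in the edgeR test, and on log2(FPKM + 1) 1 phenylpropanoid entry locus was called and 5 flavonoid loci fell. With a library left out, 23 to 27 stilbene synthase loci rose in summer and 26 to 30 fell in winter. In summer 1 phenylpropanoid entry locus rose without E-L 35 replicate 2 or E-L 38 replicate 3, and 1 to 2 flavonoid and 1 to 2 sugar loci fell. The summer fall of the terpenoid-route locus was not called without E-L 35 replicate 1 or E-L 38 replicate 3.

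In Muscat Superior, loci of the abscisic acid and sugar lists were lower at harvest in both crops, but in winter the sugar list did not pass camera. Both abscisic acid loci fell in both crops, with median log2 fold changes of -2.45 in summer and -1.66 in winter. Of 4 sugar loci 3 fell in each crop and 1 rose in winter; of 4 carotenoid loci 2 fell in summer, and 1 rose and 1 fell in winter, with equal counts adjusted over the list alone. With a library left out, 0 or 1 sugar locus rose and 1 or 2 abscisic acid loci fell in winter (1 without E-L 38 replicate 3), and 1 or 2 carotenoid loci fell in summer. Stilbene synthase rose in 5 of 30 loci in summer and in 9 in winter (3 and 6 adjusted over the list alone), with medians of 1.98 and 1.60, or 1.75 in summer with 5 loci at 0 in a group set to their bound; DESeq2 called 11 higher in summer, limma 2 on log2(FPKM + 1) and 7 on log2(FPKM + 0.1). With a library left out the counts were 1 (without E-L 35 replicate 2 or E-L 38 replicate 1) to 5 in summer and 2 (without E-L 38 replicate 2) to 12 in winter; on log2(FPKM + 1) 6 were called in winter. Phenylpropanoid entry rose in 3 of 4 loci in summer (1 on log2(FPKM + 1), and 1 to 2 with any single library left out) and 0 passed in winter, and flavonoid loci were 2 higher and 3 lower in summer (4 and 3 adjusted over the list alone or with DESeq2) and 1 and 2 in winter (2 and 2 with DESeq2). The terpenoid-route locus fell by 1.37 on the log2 scale in summer and did not pass in winter (-0.29). Camera gave in summer adjusted p = 0.0105 for stilbene synthase, 0.0113 for sugar and 0.0484 for carotenoid, and in winter 0.0322 for stilbene synthase. With an estimated correlation these were adjusted p = 0.539, 0.246, 0.248 and 0.989. The remaining lists did not pass: in summer phenylpropanoid entry had 0.0822 and flavonoid 0.199, and in winter sugar had 0.133 (0.857 with an estimated correlation) and the other 3 had 0.976. Called genes numbered 6741 in summer (3241 higher, 3500 lower) and 9115 in winter (4458 and 4657), and 83.2% of the 3928 called in both changed the same way. With near-identical libraries summed 5329 genes were called in winter, and on log2(FPKM + 0.1) 38.6% of winter calls were higher, against 48.9% in the edgeR test.

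The ripening change was compared between crops directly, where lower means a smaller E-L 38 to E-L 35 ratio in winter. In Victoria 29 of 30 stilbene synthase loci (30 adjusted over the list alone), all 4 phenylpropanoid entry loci (4) and 8 of 15 flavonoid loci (9) were lower and 0 of them higher. In the sugar list 1 locus was higher and 3 were lower, and in the carotenoid list 1 and 1, the same adjusted over the list alone. In the camera test adjusted p was 3.23e-14 for stilbene synthase and 0.0135 for both phenylpropanoid entry and flavonoid, or 0.134, 0.134 and 0.271 with an estimated correlation, and 0.0989 and 0.271 for sugar and carotenoid. In Muscat Superior 0 stilbene synthase and 0 phenylpropanoid entry loci passed, 1 flavonoid locus was lower, and 2 carotenoid loci and the terpenoid-route locus were higher, again with equal counts. Of its sugar loci 2 were higher and 1 lower (2 and 2 adjusted over the list alone), and no list passed camera (adjusted p from 0.401 to 0.974). On log2(FPKM + 1) 3 flavonoid loci were lower, 1 carotenoid locus was higher, and sugar loci were 1 higher and 2 lower; DESeq2 called 1 stilbene synthase locus higher and 1 lower. With a library left out, 28 or 29 stilbene synthase and 5 (without winter E-L 35 replicate 1) to 9 flavonoid loci were lower in Victoria, and 0 (without summer E-L 38 replicate 1) to 2 sugar and 1 to 2 carotenoid loci higher in Muscat Superior. Called genes numbered 8435 in Victoria (3922 higher, 4513 lower) and 5340 in Muscat Superior (2607 and 2733). With near-identical libraries summed 2579 genes were called in Muscat Superior. On log2(FPKM + 0.1) 59.8% of Victoria calls were higher, against 46.5%, with all genes shifted by 0.18, and in Muscat Superior 35.7%, against 48.8%, with a shift of -0.11.

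Averaged over crops and stages, Muscat Superior had more flavonoid and less stilbene synthase transcript than Victoria. Of 15 flavonoid loci 11 were higher and 3 lower, with a median log2 fold change of 0.73, and of 30 stilbene synthase loci 1 was higher and 21 lower (1 and 22 adjusted over the list alone), with a median of -1.35. The latter did not hold in each group: in winter the summed stilbene synthase level was higher in Muscat Superior at E-L 36 (516 ± 204 against 340 ± 31.9 CPM) and at E-L 38 (194 ± 119 against 101 ± 44.4 CPM; SD, n = 3). Phenylpropanoid entry had 2 loci higher and 1 lower, carotenoid 2 and 1, sugar 1 and 2, abscisic acid 0 and 0, and the terpenoid-route locus was lower (-0.87); these counts, and those of flavonoid, were equal adjusted over the list alone. On both FPKM scales 0 sugar loci and 1 carotenoid locus were higher. Camera gave adjusted p = 0.00115 for flavonoid and 0.00107 for stilbene synthase; with an estimated correlation both had adjusted p = 0.431. The cultivars differed in 12345 genes, 6195 higher and 6150 lower in Muscat Superior. With the replicate number as a block 8221 genes were called. The blocks lie within a cultivar, so that fit compares a reference replicate number of each cultivar and not the means over replicates. On log2(FPKM + 0.1) the median of all genes shifted by -0.10 and 36.3% of calls were higher, against 50.2% in the edgeR test.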

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

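The test of a single winter library for stilbene synthase, the splits with near-identical libraries kept together and the counts with them summed were chosen only after the results were seen. The 8 results here stand because an interaction test found that the crop effect or the ripening change differed between groups. The crop effect differed between cultivars in 3567 genes at E-L 35, 3688 at E-L 36 and 3304 at E-L 38, or 935, 1000 and 2006 with near-identical libraries summed. Genes with a called interaction that were higher in winter in a cultivar and lower in the other numbered 240, 413 and 274 at these stages. The ripening change differed between crops in 8435 genes in Victoria and 5340 in Muscat Superior.

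Other splits of the same libraries were tested in fits to the groups of each contrast alone. These splits take each library as a sample of its own, so they were repeated with near-identical libraries kept together. For the crop effect between cultivars at E-L 35, 1 of 100 splits, the real one, gave as many genes (5220, highest other 4467). With near-identical libraries kept together only 20 splits exist, too few for a share under 0.05 (2 gave as many, highest other 9240). At E-L 36 and E-L 38, 5 of 100 splits did (real 1983 and 2738, highest other 3125 and 4149), so chance cannot be excluded by this test. The 4 larger splits at each of these stages kept the label of all 6 Victoria libraries and of only 2 of the 6 Muscat Superior libraries, which points to a structure of the samples: the crop difference shared by both cultivars then counts as an interaction. With near-identical libraries kept together 5 of 8 splits gave as many genes at E-L 36 (highest other 9674), too few splits for a share under 0.05, and 11 of 80 did at E-L 38 (highest other 11224). For the ripening change between crops in Victoria 1 of 100 splits reached its count (7365, highest other 4933). With near-identical libraries kept together 2 of 80 did (highest other 9817). For the cultivar comparison 1 of 40 did (12345, highest other 454), or again 1 of 40 (highest other 10774). These shares were under 0.05, without a correction for the number of such tests. In Victoria another split still called more genes than the real one, and a crop difference shared by both stages can count as an interaction. The test therefore does not exclude chance for the ripening change in Victoria. In Muscat Superior the ripening change gave 1 of 100 (7473, highest other 5875), but with near-identical libraries kept together only 20 splits exist, too few for a share under 0.05 (2 gave as many, highest other 9965). The winter and summer comparisons and the 4 ripening comparisons allow 10 splits each, too few for a share under 0.05. In the 6 former the real splits gave 7122, 7982 and 8675 genes in Victoria and 7940, 5534 and 8709 in Muscat Superior, by stage, and the highest other split gave 0. The ripening comparisons gave 7189 and 8232 in Victoria and 8426 and 10093 in Muscat Superior, summer and winter, with a highest other of 0.

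Among the crop differences in Victoria, all 30 stilbene synthase loci were higher in winter at E-L 35, and 29 had a lower ripening change in winter. The latter is not an independent result, since both use the same libraries at E-L 35. A single winter library as the source is argued against, since the lowest winter library at E-L 35 had 17.38 times the summed CPM of the highest summer library (486.6 against 27.99), though the winter libraries ranged up to 2126. How many loci moved stays open: 0 loci had whole-number counts in at least 80% of libraries, so 30 loci moving together and fewer loci whose reads were shared between near-identical copies cannot be told apart. A biological difference between the crops stays open as well and was not tested apart from season and batch.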

How the results depend on the processing

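Summing near-identical libraries and leaving out 2 summer Victoria libraries were tests chosen only after the results were seen; all other alternatives were chosen before the data were examined. Each of the 16 counts of called genes stayed within 1.5 times its value with DESeq2 size factors, the DESeq2 Wald test, limma on both FPKM scales, no count filter and a stricter filter, and none of the named fold changes turned its sign with DESeq2 size factors, the DESeq2 Wald test, limma on log2(FPKM + 1), a fit to only the groups in the contrast, the replicate number as a block or a replicate left out, the alternatives in which they were computed. Of these 392 values 12 kept their direction but lost their call: 4 in the fit to only the groups in the contrast, 5 with a replicate left out, and 1 each with the DESeq2 Wald test, limma on log2(FPKM + 1) and the block. The loci had been named for a low p-value or a large change in these same libraries. A change of sign was therefore unlikely beforehand, and these values say little about loci in general. The named fold changes and the list tests were not computed with near-identical libraries summed. Leaving out each replicate in turn moved the counts to between 0.67 and 1.26 times their value (2316 to 2381 for winter and summer Muscat Superior at E-L 35, the largest drop, and 2949 to 4631 for the crop effect between cultivars at E-L 36). With near-identical libraries summed, counts fell to 6218 for winter and summer Victoria at E-L 36 and 527 for Muscat Superior at E-L 35, to 935, 1000 and 2006 for the crop effect between cultivars at E-L 35, 36 and 38, to 5329 for ripening in winter Muscat Superior and to 2579 for its difference between crops; this alternative has fewer libraries by construction, and whether that alone lowered the counts was not tested. A fit to only the groups in the contrast gave 7940 for winter and summer Muscat Superior at E-L 35, 5534 at E-L 36 and 1983 for the crop effect between cultivars at E-L 36. The cause of these differences was not tested. The fit behind 7940 takes its spread from the libraries of that contrast alone, and all its winter libraries were near-identical, so 7940 can be too high. The replicate number as a block gave 8221 for the cultivar comparison, but the blocks lie within a cultivar. That fit sets a reference replicate number of each cultivar against the other, not the means over replicates, so it does not check the same contrast. A fold change of at least 2 leaves fewer genes by construction: by stage, 3395, 4640 and 5271 for winter and summer Victoria and 1167, 3686 and 3927 for Muscat Superior, and for ripening 3302 and 4903 in summer and winter Victoria and 2604 and 3976 in Muscat Superior. Without replicate 1 of summer Victoria at E-L 36 and E-L 38 the 7 counts that use those groups stayed between 0.98 and 1.33 times their value. Replicate numbers do not pair libraries: deviations from the group mean correlated between same-numbered libraries with a median of 0.002 in Victoria and 0.008 in Muscat Superior, and 15 of 36 libraries correlated best with their own number. Of the 30 list tests between crops, 8 lost their call with an estimated correlation. In 11 that did not pass camera, fry, which tests against no change, did. Depth limits the weakest signals, since the floor of 3 counts was 0.161 to 0.533 CPM. In simulated data 18% of genes changed by a factor of 1.5 were recovered, but few genes were changed there. It gave 148 edgeR calls, against 8315 for winter and summer Victoria at E-L 35, so the adjusted threshold was stricter. That share is therefore no measure of depth or of sensitivity in the real comparison.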

Other observations

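The tests of repeated measurement, winter depth and uniform winter berries, and the permutation with near-identical libraries averaged, were chosen only after the results were seen; the other tests here were set out before. Summed levels of the smaller lists are given here as values: neither the sugar nor the carotenoid list passed camera between crops in any of the 6 comparisons (adjusted p from 0.0777 to 0.721). The sugar list in Victoria had 1990 ± 345 CPM in winter and 996 ± 21.0 in summer at E-L 35 (SD, n = 3), but 505 ± 9.34 against 1180 ± 387 at E-L 36 and 420 ± 133 against 1080 ± 378 at E-L 38. In Muscat Superior it had 1640 ± 43.6 against 1360 ± 58.4 at E-L 35, 956 ± 41.3 against 999 ± 307 at E-L 36 and 385 ± 93.8 against 619 ± 59.1 at E-L 38. Most of the sugar sum lay in 1 locus, VIT_218s0122g00850, wherever its values are given here. In Victoria it had 361 against 943 CPM at E-L 36 and 295 against 917 at E-L 38. In Muscat Superior at E-L 38 it had 297 against 599, where the sum fell although 2 of the 4 loci rose and 1 fell. The carotenoid list in Victoria had 94.1 ± 7.65 CPM in winter against 77.4 ± 20.0 in summer at E-L 35, 119 ± 4.86 against 48.4 ± 18.8 at E-L 36 and 108 ± 13.4 against 59.5 ± 20.9 at E-L 38. In Muscat Superior it had 95.8 ± 2.51 against 158 ± 4.26, 85.2 ± 21.7 against 197 ± 86.8 and 96.9 ± 17.2 against 110 ± 52.7 at these stages. Most of these summer sums lay in 1 locus, VIT_202s0087g00930, with 112, 173 and 95.2 CPM in summer and 44.7, 31.5 and 28.6 in winter. The sums therefore do not give the direction of the list. Of its 4 loci 0 rose and 1 fell at E-L 35, but 2 rose and 1 fell at E-L 36 and at E-L 38. The terpenoid-route locus in Muscat Superior had 52.6 ± 0.689 against 22.1 ± 5.20 CPM at E-L 36.

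A hypothesis was that winter and summer berries of the same stage differ in how far they have ripened. A ripening score was the mean log2 CPM of genes that rose at least 2-fold from E-L 35 to E-L 38 in the summer berries of the other cultivar, minus that of genes that fell (1021 and 1583 genes for Victoria, 1210 and 2092 for Muscat Superior). A two-sided permutation test within the 6 combinations of cultivar and stage (100000 resamples) gave p = 0.018 for the summed absolute difference of 1.75 between crops, taking each library as a sample of its own. With near-identical libraries averaged, which leaves 2 winter groups with 1 value each, p was 0.15, so the hypothesis stays open. Winter minus summer was 0.62, 0.03 and 0.29 in Victoria and 0.12, -0.30 and -0.38 in Muscat Superior at E-L 35, 36 and 38, and the summer span from E-L 35 to E-L 38 was 1.80 and 1.52. Exact permutation tests of the single stages gave p from 0.1 to 1.0, where 3 libraries against 3 cannot go below 0.1. A direct effect of season on these genes would move the score too, and was not tested apart.

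Of the 18 winter replicate pairs 8, and of the 18 summer pairs 0, differed by little more than counting noise. Whether a library was sequenced more than once was not decided. Over genes with whole-number counts these pairs had a median chi-square of 1.48 per degree of freedom (1.321 to 1.78). Counting noise alone gave 0.99 in simulated data. That simulation held no other technical spread, and the counting program is not given, so the value expected of a repeated library is not known. Lower depth of the winter libraries is argued against as the whole cause: with every library thinned to the lowest total, 17 of the 18 summer pairs stayed at 2 or above (median 7.52), and the other, replicates 1 and 2 of summer Muscat Superior at E-L 35, fell to 1.64, where the near-identical pairs reached at most 1.49. Other explanations stay open as well. More uniform berries in the winter crop cannot be told apart: the closest winter pair lay below the closest summer pair in 6 of 6 combinations of cultivar and stage, but 4 of these hold the near-identical pairs themselves, and only 2 do not (8.42 against 9.54 and 4.91 against 7.36). Repeated measurement of one RNA or berry pool cannot be told apart either. From 20 to 200 up to 1000 to 5000 counts the chi-square grew by at most 1.28 times in these pairs, but pairs picked for a low chi-square have a low ratio by construction, and a summer pair that was not picked had 1.46. No label tells whether a pool was measured more than once.

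Replicate 1 of summer Victoria at E-L 36 lay nearer to E-L 38 than to its own group. An exchange of labels with E-L 38 replicate 1 is a candidate explanation. On the ripening score that library was closer to E-L 36 replicates 2 and 3 than to its own group by 0.32. That is only just above the mean spread of 0.29. The score cannot decide on an exchange, since E-L 38 replicate 2, at 1.02, also lay near the mean of 0.96 of E-L 36 replicates 2 and 3. Replicate 3 of E-L 38 scored 1.53. By correlation E-L 38 replicate 1 did not separate, at 0.9822 and 0.9831 with E-L 36 and 0.9830 and 0.9712 with its own group. On component 4 it had -25.7, beside -26.7 and -27.7 in E-L 36 replicates 2 and 3 and apart from -5.6 and -0.1 in its own group. On component 3 (12.9% of variance) it had 28.2, beside 23.4 and 29.2 in E-L 36 replicates 2 and 3. The others of its own group had 36.8 and 52.2 there, and E-L 36 replicate 1 had 49.6. On components 1 and 2 E-L 38 replicate 1 lay with its own group. The stilbene synthase sum of E-L 36 replicate 1 (34.47 CPM) was below those of E-L 38 replicates 2 and 3 (213.7 and 236.1). The sugar sum went with an exchange: E-L 38 replicate 1 had 1464 CPM, beside 1397 and 1402 in E-L 36 replicates 2 and 3. In E-L 36 replicate 1 it was 729.8, and in E-L 38 replicates 2 and 3 it was 1068 and 709.4. Uneven ripening of the sampled berries cannot be told apart from an exchange. The deviation of E-L 36 replicate 1 correlated with the summer ripening change of Muscat Superior at 0.16 across genes, which decides nothing.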
